A study of Drosophila melanogaster with 3 samples.

How the data were processed

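RNA was sequenced from wing imaginal discs, the larval epithelia that form the adult wing and dorsal thorax, of Drosophila melanogaster that, per the labels, carried 1 copy of the apterous-GAL4 driver. Per the labels' protocols, larvae were raised at 25 °C to the wandering stage, about 5 days after egg laying, each sample pooled 100 to 120 discs dissected for 20 min, RNA was extracted with TRIzol, and TruSeq libraries were read as pairs of 50 nt. There were 3 libraries, all of 1 group, so the design holds no comparison between conditions. The comparisons made were between genes and between families of genes, with the spread between the 3 libraries as the error. The labels do not say whether the 3 RNA samples came from separate cultures, so the spread between them may be partly technical.

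The deposited table holds FPKM values (fragments per kilobase of exon, scaled by library size) for 17611 genes, made by the authors before deposition, with 1 column per library and no pooled columns. The columns were matched to the samples by their number only, because the prefix of the column names, w118, is in no label. The genotype is given as the labels state it, and whether the prefix stands for the same stock is open, which bears on how the values of ap and w are read. Per the submitters' processing notes, the tools were CASAVA 1.8, FastQC 0.11.8, STAR 2.7.6a, featureCounts 1.6.0 and DESeq2 (version not given), and the genome build was dm6. The annotation, the treatment of reads that match several places and the strand setting of the counting are not given in the sources used here.

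Each FPKM value was multiplied by the gene's merged exon length in Ensembl release 115 (assembly BDGP6, which shares dm6 coordinates). Of the 17611 genes, 17551 had a length. In each library these products were whole multiples of 1 step for over 99.7% of the genes above 0 (tolerance 0.01 of a read), and 34 genes were not whole in some library. All 114 receptor genes were whole. The steps gave 26454949, 26098531 and 25047773 recovered reads or read pairs in libraries 1, 2 and 3. The library sizes implied by the steps, relative to their geometric mean, were 1.03, 1.00 and 0.967. Median-of-ratios size factors computed from the recovered reads were also 1.03, 1.00 and 0.967, so the deposited values are scaled by a size factor per library and not by the plain read total. The recovered reads were used for depth, for limits on genes without a read and for alternatives, and not for the main test.

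Lists of genes were fixed before the data were examined: 114 genes of G protein-coupled receptors (GPCRs) in 9 lists, 24 lists of signalling genes, disc genes and markers of other tissues, and 21 pairs of genes. The receptor lists were written from general knowledge and may be incomplete. All symbols matched the table or its synonyms except 1, a synonym of a receptor that had been placed among the ligands, which was left out. A receptor gene was called detected at 1 FPKM or more in each of the 3 libraries. It was also tested with limma 3.58.1 in R 4.3.3, as a one-sided moderated test of mean log2(FPKM + 0.1) against the same transform of 1 FPKM, with Benjamini-Hochberg adjustment over the 13909 genes above 0 in any library and a threshold of 0.05. Differences on this scale understate changes of genes near the pseudocount of 0.1. The rule written for a table with counts did not apply, because the table holds FPKM only.

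Families were compared by Fisher's exact test (two-sided) on the number of detected genes in a list against all other receptor lists, adjusted over the 9 lists. Genes are the units of that test and are not replicates. The median level of a list was placed among 10000 random lists of the same size drawn from all genes, and its median SD among 10000 random lists matched on mean level. Log2 ratios of paired genes were taken of FPKM + 0.1 within each library, and with 3 libraries an exact sign-flip permutation test cannot give a two-sided p below 0.25. Limits for genes with no read are those allowed by 3 reads over the 3 libraries together, and cover counting error only.

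The named genes were set by rule: the 25 receptors with the highest mean, the 3 highest of each list, all of class F, the paired genes, the 10 highest genes of all, the 10 genes of at least 5 FPKM with the largest SD of log2(FPKM + 0.1), and the 3 receptors of at least 1 FPKM with the largest SD. Genes outside that rule, such as Hsp70Ab, Hsp22, gl, AkhR and most receptors without reads, were named after their values were seen. Coordinates and overlaps of exons were taken from the Ensembl annotation.

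The limma test was checked on 13387 simulated genes with known levels. It called 72% of 50 genes set at 1.25 FPKM, 96% of 50 at 1.5 FPKM, 98% of 50 at 2 FPKM and 100% of 50 at 4 FPKM, and 6.5% of 200 genes set at exactly 1 FPKM. All simulated genes shared the same dispersion, the median over genes with a mean of at least 50 reads. These shares therefore do not carry over to genes with a larger spread between libraries. The alternatives were other limits, other pseudocounts, TPM values, other library sizes, a filter on low values, a read minimum, a variance trend, voom weights on the recovered reads, and leaving out each library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.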

Results

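The data are gene expression values of wing discs from wandering larvae with, per the labels, the genotype w;apGAL4/+, in which the GAL4 driver follows the apterous gene of the dorsal wing compartment. The series was made to survey which G protein-coupled receptor genes this tissue expresses. The 3 libraries held 25047773 to 26454949 recovered reads each. Of 17611 genes listed, 7786, 7999 and 7919 reached 1 FPKM in libraries 1, 2 and 3, and 7556 did so in all 3. Across the 13909 genes above 0 in any library, Pearson's r of log2(FPKM + 0.1) was 0.974 between libraries 1 and 2, 0.979 between 1 and 3 and 0.979 between 2 and 3, and Spearman's rho was 0.948, 0.958 and 0.959. These correlations are across genes, which are not replicates. Read counts of each pair differed by more than sampling noise (chi-square per degree of freedom 17.6, 23.8 and 28.1), so no library was a copy of another, and the labels name the 3 as separate samples. For the median gene the chi-square was 3.14, 3.99 and 4.08 times its expected median, so the typical gene varied less than those means show. That spread may still be technical.

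Most receptor genes had few or no reads in the discs, and a minority stood at 1 FPKM or more throughout. Of 114 receptor genes, 25 (21.9%) reached 1 FPKM in every library, 72 had some reads but not that level throughout, and 17 had no read in any library. The adhesion receptor gene Cirl, a latrophilin, was the highest at 161 ± 7.50 FPKM (SD, n = 3). It was followed by fz2, a Wnt receptor, at 94.8 ± 5.46 FPKM, mth at 80.03 ± 6.01 FPKM, mthl5 at 57.4 ± 1.78 FPKM and fz, the planar polarity and Wnt receptor, at 53.3 ± 1.65 FPKM (SD, n = 3 each). These 5 genes made up 55.8% of the summed FPKM of all receptor genes. By the limma test 24 receptor genes lay above 1 FPKM with adjustment over all genes, and 23 adjusted over the list alone. All 24 were among the 25 detected. The remaining detected gene, rk, the receptor of the cuticle-tanning hormone bursicon, stood at 1.30 ± 0.224 FPKM, with a limma adjusted p of 0.0519. Exons of NimC2 on the other strand cover 9.78% of the rk exons. The weakest call, mthl2 at 1.28 ± 0.192 FPKM, had a limma adjusted p of 0.046 and was lost when any library was left out.

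**Figure D1:**
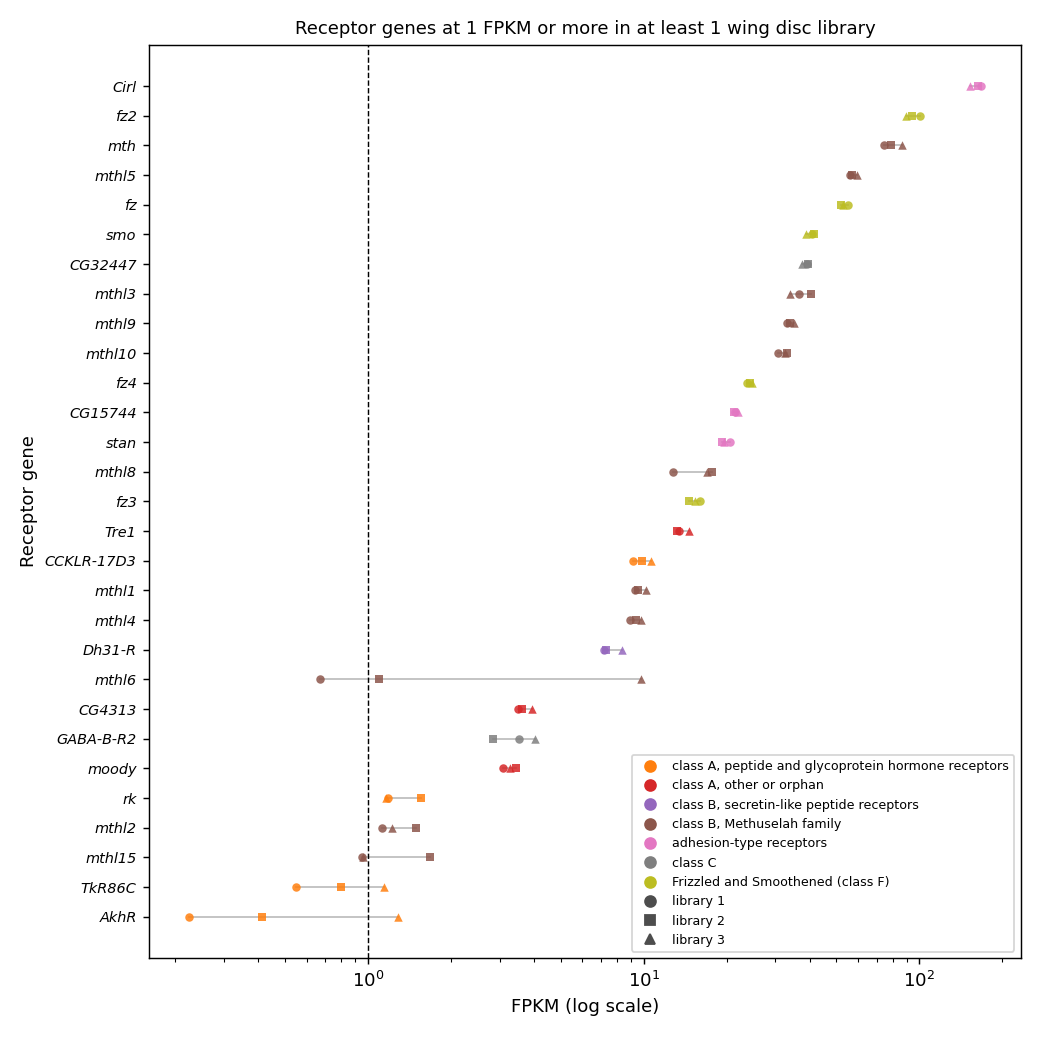
FPKM (x axis, log scale) of each receptor gene (y axis) that reached 1 FPKM in at least 1 library. Each marker is 1 library, its shape gives the library, its colour the receptor list, grey lines join the lowest and highest library, and the dashed line is 1 FPKM. Most genes varied little between libraries, with a median ratio of highest to lowest of 1.10 among the 25 detected genes, while mthl6 ran from 0.672 to 9.77 FPKM.

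All 5 genes of class F, the Frizzled receptors and Smoothened, were expressed in every library. After fz2 and fz came smo, the signal transducer of the Hedgehog pathway, at 40.4 ± 1.28 FPKM, fz4 at 24.3 ± 0.52 FPKM and fz3 at 15.3 ± 0.686 FPKM. The 5 genes were detected against 20 of 109 other receptor genes (18.3%; Fisher's exact test, p = 0.000362, adjusted p = 0.00326 over 9 lists). Genes are the units of these family tests and are not independent replicates. Within libraries, fz was lower than fz2 with a log2 ratio of -0.83 ± 0.06 (SD, n = 3), and fz2 was higher than fz4 by 1.96 ± 0.11 and higher than fz3 by 2.62 ± 0.07. The log2 ratio of fz to fz3 was 1.79 ± 0.02, and that of smo to fz was -0.40 ± 0.07. smo and ptc, which encodes the Hedgehog receptor that holds Smoothened inactive, lay close together, with a log2 ratio of 0.32 ± 0.12. Each ratio kept its sign in 3 of 3 libraries, and the exact sign-flip permutation p was 0.25 for each, the smallest that 3 libraries allow. The order of smo and ptc depended on dividing by gene length, since the log2 ratio of recovered reads was -0.14. In the annotation fz2 lies at chromosome 3L 19140975 to 19235373, fz at 3L 14274343 to 14368639, smo at 2L 277582 to 282167, fz4 at X 7106272 to 7110321 and fz3 at X 769945 to 784222 (dm6 coordinates). Exons of genes on the opposite strand cover 27.1% of the exon length of smo, and whether the counting used strand is not given.

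The Methuselah family of class B receptors supplied the largest number of expressed receptor genes. Of its 16 members 9 were detected, against 16 of 98 other receptor genes (56.2% against 16.3%; Fisher's exact test, p = 0.00125, adjusted p = 0.00564 over 9 lists). After mth (chromosome 3L 343378 to 346957) and mthl5 (3R 11883938 to 11887168), mthl3 stood at 37.0 ± 3.20 FPKM, mthl9 at 34.1 ± 0.955 FPKM, mthl10 at 32.1 ± 1.30 FPKM and mthl8 at 15.8 ± 2.65 FPKM. The lower members were mthl1, a receptor of the secreted protein Fog, at 9.67 ± 0.466 FPKM, mthl4 at 9.37 ± 0.457 FPKM and mthl2. The neighbouring genes mthl9, mthl10 and mth lie at 3L 329822 to 346957. mthl11 and mthl13 had no read in any library. The largest spread in the family was that of mthl6, at 0.672, 1.09 and 9.77 FPKM in libraries 1, 2 and 3, and mthl15 also fell on both sides of 1 FPKM, at 0.953, 1.68 and 0.959 FPKM.

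Among the adhesion-type receptors 3 of 6 genes were detected, a share that did not pass the test against the other lists (Fisher's exact test, adjusted p = 0.213). They were Cirl (chromosome 2R 8614722 to 8625203), CG15744 at 21.5 ± 0.391 FPKM and stan, the seven-pass cadherin of planar polarity also called flamingo, at 19.8 ± 0.699 FPKM. Cirl exceeded stan by a log2 ratio of 3.02 ± 0.06 (SD, n = 3), and stan lay under fz with a log2 ratio of -1.43 ± 0.01. The order of stan and fz depended on gene length, as the log2 ratio of recovered reads was 0.40. In class C, 2 of 9 genes were detected (Fisher's exact test, adjusted p = 1). CG32447 stood at 38.7 ± 0.949 FPKM and GABA-B-R2, a metabotropic GABA receptor subunit, at 3.47 ± 0.613 FPKM. Its partner subunit gene GABA-B-R1 had 2 reads in all, at 0.00444 FPKM, and the log2(FPKM + 0.1) ratio of GABA-B-R1 to GABA-B-R2 was -5.08 ± 0.26, with -2.15 and -8.02 for pseudocounts of 1 and 0.01. The Fog receptor gene smog stood at 0.0865 ± 0.0213 FPKM, below mthl1 in 3 of 3 libraries (log2 ratio of mthl1 to smog 5.72 ± 0.14, with 3.29 and 6.67 for pseudocounts of 1 and 0.01).

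Receptors for amines and for most peptides were scarcely expressed. None of the 21 biogenic amine and adenosine receptor genes was detected, against 25 of 93 other receptor genes (Fisher's exact test, p = 0.00641, adjusted p = 0.0144 over 9 lists). The highest of them was the adenosine receptor gene AdoR at 0.0997 ± 0.0587 FPKM, followed by the dopamine receptor gene Dop1R2 at 0.0916 ± 0.095 FPKM and the serotonin receptor gene 5-HT7 at 0.0402 ± 0.0247 FPKM. An antisense gene covers 60.1% of the AdoR exons. Of 34 peptide and glycoprotein hormone receptor genes 2 were detected, against 23 of 80 others (5.88% against 28.8%; Fisher's exact test, p = 0.00628, adjusted p = 0.0144). These were CCKLR-17D3, a cholecystokinin-like receptor, at 9.87 ± 0.745 FPKM (chromosome X 18764483 to 18774027), and rk. Its paralog CCKLR-17D1 had no read. TkR86C, a tachykinin-type receptor, was at 0.83 ± 0.298 FPKM and passed 1 FPKM in library 3 alone. AkhR, the receptor of the fat-mobilising adipokinetic hormone, stood at 0.224, 0.412 and 1.28 FPKM in libraries 1, 2 and 3. Lgr3, the receptor of the growth-coordinating peptide Ilp8, had 2 reads in all, and Lgr4 stood at 0.346 ± 0.254 FPKM, with 29.2% of its exons covered by a gene on the other strand. The peptide receptor result did not pass the test when 1 library at 1 FPKM was enough for detection (adjusted p = 0.0778) or when 10 reads in each library were (adjusted p = 0.0653).

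Among the remaining class A genes, 3 of 11 orphan or other receptors were detected (adjusted p = 0.905). Tre1, which guides migrating germ cells in embryos, stood at 13.7 ± 0.729 FPKM, CG4313 at 3.68 ± 0.232 FPKM and moody, a receptor of the glial blood-brain barrier, at 3.27 ± 0.177 FPKM. Exons of Actn and usp on the other strand cover 11.1% of the CG4313 exons. moody lies within the span of CG4313 on chromosome X (2041868 to 2055414). None of 7 opsin genes was detected (adjusted p = 0.516). Rh5 was at 0.859 ± 0.105 FPKM, Rh6 at 0.0271 FPKM and Rh4 at 0.0188 FPKM. Over all of class A, 5 of 73 genes were detected. Of 5 secretin-like class B receptors only Dh31-R, the receptor of a calcitonin-like diuretic hormone, was detected, at 7.61 ± 0.645 FPKM (adjusted p = 1), while Dh44-R2 was at 0.0994 FPKM and Pdfr at 0.0501 FPKM. The 17 receptor genes without a read, among them the dopamine receptor genes Dop1R1 and Dop2R, have upper limits of 0.00265 to 0.0292 FPKM, which cover counting error only.

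**Figure D2:**
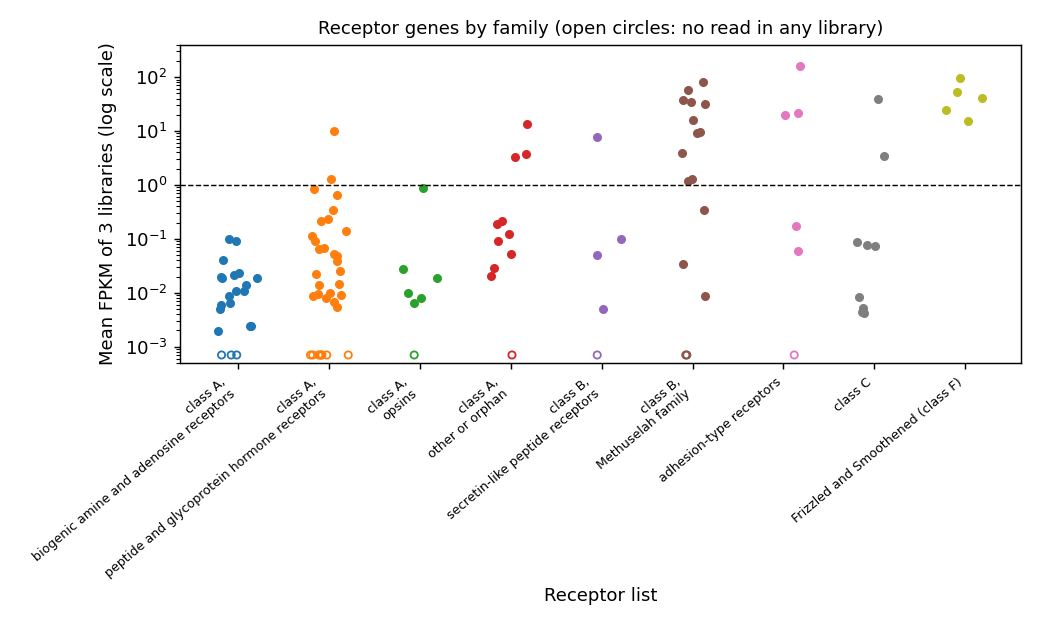
Mean FPKM of the 3 libraries (y axis, log scale) for each of the 114 receptor genes, in columns by receptor list (x axis). Filled circles are genes with reads, open circles are genes without a read, placed under the axis range of the others, and the dashed line is 1 FPKM. All 5 class F genes lie above the line and all 21 amine and adenosine receptor genes below it.

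Most listed genes for proteins that act downstream of these receptors were detected. Of 11 G protein subunit genes 7 were detected, led by Galphai at 129 ± 3.03 FPKM, Ggamma1 at 111 ± 3.76 FPKM and Galphas, which activates adenylyl cyclase, at 97.1 ± 1.92 FPKM. Gbeta13F stood at 72.8 ± 2.75 FPKM and cta, the G alpha subunit of Fog signalling, at 28.9 ± 1.54 FPKM, while Galphao was at 10.5 ± 0.197 FPKM and Galphaq at 8.92 ± 0.28 FPKM. Exons of another gene on the same strand cover 44.1% of Galphaq. The eye subunits were nearly absent, with Ggamma30A at 0.0368 FPKM and no Gbeta76C read (upper limit 0.0264 FPKM). The log2 ratio of Galphas to Galphai was -0.41 ± 0.05, of Galphas to Galphaq 3.43 ± 0.07, of Galphao to Galphai -3.61 ± 0.05 and of cta to Galphaq 1.68 ± 0.05 (SD, n = 3). With the pseudocount, Gbeta13F exceeded Gbeta76C by 9.51 ± 0.05 and Ggamma1 exceeded Ggamma30A by 9.67 ± 0.25. With pseudocounts of 1 and 0.01 these were 6.20 and 12.8 for the first pair and 6.75 and 11.3 for the second.

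Of 13 receptor kinase, arrestin and regulator genes 9 were detected. The G protein-coupled receptor kinase gene Gprk1 stood at 66.7 ± 1.64 FPKM, above Gprk2 at 21.8 FPKM (log2 ratio of Gprk2 to Gprk1 -1.61 ± 0.05). Axn, the Wnt pathway scaffold, was at 40.4 ± 0.843 FPKM and RhoGEF2 at 38.1 ± 1.20 FPKM. The non-visual arrestin gene krz stood at 27.4 ± 1.67 FPKM, with log2 ratios of 4.82 ± 0.05 to the visual arrestin gene Arr2 and of 7.91 ± 0.15 to Arr1, which had 3 reads in all, so that the second ratio ranged from 4.81 to 10.3 with pseudocounts of 1 and 0.01. Of 17 second messenger genes 14 were detected, with the protein kinase A catalytic gene Pka-C1 at 27.4 ± 1.26 FPKM, the phospholipase C gene norpA at 19.7 ± 1.93 FPKM and the regulatory subunit gene Pka-R1 at 18.3 ± 0.363 FPKM. Pka-C1 exceeded Pka-C3 by a log2 ratio of 2.45 ± 0.13. The median level of the regulators ranked at percentile 96.7 among random lists of the same size, that of the second messenger enzymes at 91.6 and that of the G protein subunits at 90.3. With the lists and the random lists both limited to genes with a mean of at least 0.1 FPKM, these percentiles were 85.7, 32.5 and 93.3. The 114 receptor genes ranked at percentile 0, below all 10000 random lists, and the 40 of them with a mean of at least 0.1 FPKM ranked at percentile 5.92 among lists limited in the same way.

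Most Wnt, Hedgehog and Fog-type ligand genes were expressed, and peptide precursors mostly were not. Of 9 Wnt, Hedgehog and Fog-type ligand genes 7 were detected, among them wg at 37.8 ± 1.71 FPKM, Wnt5 at 35.2 ± 1.37 FPKM and hh at 35.2 ± 2.51 FPKM. fog stood at 3.69 ± 0.283 FPKM. Of 37 neuropeptide and peptide hormone genes 2 were detected, ITP at 13.6 ± 0.17 FPKM and ETH at 10.2 ± 0.657 FPKM. An antisense gene covers 90.5% of the ETH exons. CCHa2 stood at 1.26 ± 0.712 FPKM. Of 9 transmitter synthesis genes 3 were detected, ple, Ddc and Tdc1. ple and Ddc, enzymes of dopamine synthesis that also act in cuticle formation, were highest in library 2, at 11.04 and 8.65 FPKM against 3.69 and 2.62 FPKM in library 1 and 3.67 and 2.14 FPKM in library 3. Tdc1 was at 2.71 ± 0.243 FPKM.

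Genes that pattern the wing disc were expressed in every library, with 36 of 36 detected. The Dpp receptor gene tkv stood at 129 ± 1.8 FPKM, fng at 128 ± 4.66 FPKM and ci, the Hedgehog pathway transcription factor, at 122 ± 1.14 FPKM. ap, the gene of the driver that the labels name, was at 80.7 ± 1.78 FPKM. The eye colour gene w, a marker often carried by transgene vectors, stood at 278 ± 10.2 FPKM. Ubx, which specifies the haltere, was at 2.11 ± 0.302 FPKM, abd-A at 0.318 FPKM and Abd-B at 0.0151 FPKM. Of 6 eye disc markers 2 were detected, as eya stood at 8.74 ± 0.147 FPKM and so at 7.54 ± 0.563 FPKM, while ey was at 0.0907 FPKM and gl had no read. Of 15 ecdysone response genes 12 were detected, led by ImpE2 at 3213 ± 51.0 FPKM, br at 128 ± 5.93 FPKM and ImpE1 at 99.6 ± 7.25 FPKM. Of 13 heat shock genes 7 were detected, from Hsp23 at 2281 ± 194 FPKM, the chaperone gene Hsp83 at 1249 ± 24.0 FPKM and Hsp27 at 1177 ± 51.1 FPKM to Hsp70Ab at 4.50 ± 0.738 FPKM, the median of the list, and Hsp22 is listed at 0. The inducible Hsp70 genes are near-identical copies whose reads may be split, so their values are uncertain. The highest genes of all were mt:lrRNA at 26381 ± 1268 FPKM, RpL41 at 9939 ± 347 FPKM and eEF1alpha1 at 5522 ± 170 FPKM, followed by mt:CoIII, RpS27A, RpL39, ImpE2, mt:CoI, RpL23 and RpLP2. All 8 housekeeping genes were detected, and of these alphaTub84B stood at 2657 ± 165 FPKM and Act5C at 2462 ± 73.9 FPKM.

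Markers of tissues attached to the disc were present in every library. The median SD of log2(FPKM + 0.1) was 0.08 for the myoblast markers, 0.09 for the tracheal markers and 0.21 for the hemocyte markers, against 0.07 for the detected receptor genes. Among random lists matched on level, these medians ranked at percentiles 71.2, 87.8, 67.4 and 69.3. The receptor genes were chosen for their level in every library, while the marker lists and the random lists were not. All 7 myoblast markers were detected, with Ama at 117 ± 6.68 FPKM, Him at 18.6 ± 1.14 FPKM and stumps at 12.5 ± 0.76 FPKM. All 6 tracheal markers were detected, with the chitin deacetylase genes verm at 235 ± 17.8 FPKM and serp at 81.4 ± 4.31 FPKM and the chitin-binding gene Gasp at 63.9 ± 7.14 FPKM, although these 3 are not limited to trachea. Of 7 hemocyte markers 6 were detected, with crq at 19.5 ± 2.37 FPKM, He at 7.01 ± 0.376 FPKM and Pxn at 5.24 ± 0.794 FPKM. Of 5 glial genes 2 were detected: Gli and nrv2 stood at 78.7 ± 3.14 and 78.6 ± 1.6 FPKM, and repo, the pan-glial factor, at 0.0559 FPKM. Gli and nrv2 are also septate junction genes of epithelia. Of 8 neuronal genes only elav was detected and stood at 2.65 ± 0.0857 FPKM, Syt1 at 0.512 FPKM and futsch at 0.501 FPKM. None of 5 germline genes was detected, and the highest were vas at 0.355 FPKM, bam at 0.126 FPKM and nos at 0.0388 FPKM. Of 9 larval muscle genes 7 were detected, with Act57B at 32.8 ± 7.25 FPKM, Mlc2 at 14.7 ± 3.61 FPKM and Act87E at 7.68 ± 0.397 FPKM. The median SD of the muscle genes was 0.34, at percentile 92.7 of random lists matched on level.

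Transcripts of gut, salivary gland and fat body differed widely between the libraries. Of these lists, 2 of 8 digestive genes, 5 of 6 glue genes and 7 of 7 fat body genes were at 1 FPKM or more in every library. The digestive protease gene Jon65Aiv stood at 4.11, 542 and 218 FPKM in libraries 1, 2 and 3, Jon65Aiii at 1.89, 282 and 124 FPKM and the trypsin gene alphaTry at 0.175, 38.4 and 21.4 FPKM. The glue gene Sgs7 was at 60.7, 414 and 137 FPKM, Sgs5 at 26.6, 152 and 54.1 FPKM and Sgs3 at 12.05, 108 and 32.6 FPKM. The larval serum protein genes of the fat body were highest in library 3, with Lsp1gamma at 123, 216 and 940 FPKM, Lsp2 at 123, 193 and 657 FPKM and Lsp1beta at 92.5, 161 and 474 FPKM. The 7 fat body markers took 0.149%, 0.239% and 0.655% of the reads of libraries 1, 2 and 3. The median SD of log2(FPKM + 0.1) was 2.65 for the digestive list, 1.33 for the glue genes and 1.19 for the fat body list, each above all 10000 random lists matched on level. It was 0.07 for the 25 detected receptor genes (percentile 69.3) and 0.05 for the disc patterning genes (percentile 26.8). The 25 receptor genes had to reach 1 FPKM in every library, which leaves out variable genes such as mthl6. The other lists and the random lists had no such filter, so the low receptor spread is partly set by the selection. Of the 4 receptor genes on both sides of 1 FPKM, AkhR, TkR86C and mthl6 were highest in library 3 and mthl15 in library 2. The number of detected receptor genes was 25 without library 3 and 25 without library 2, the same genes in both cases, and 26 without library 1, which added mthl6.

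**Figure D3:**
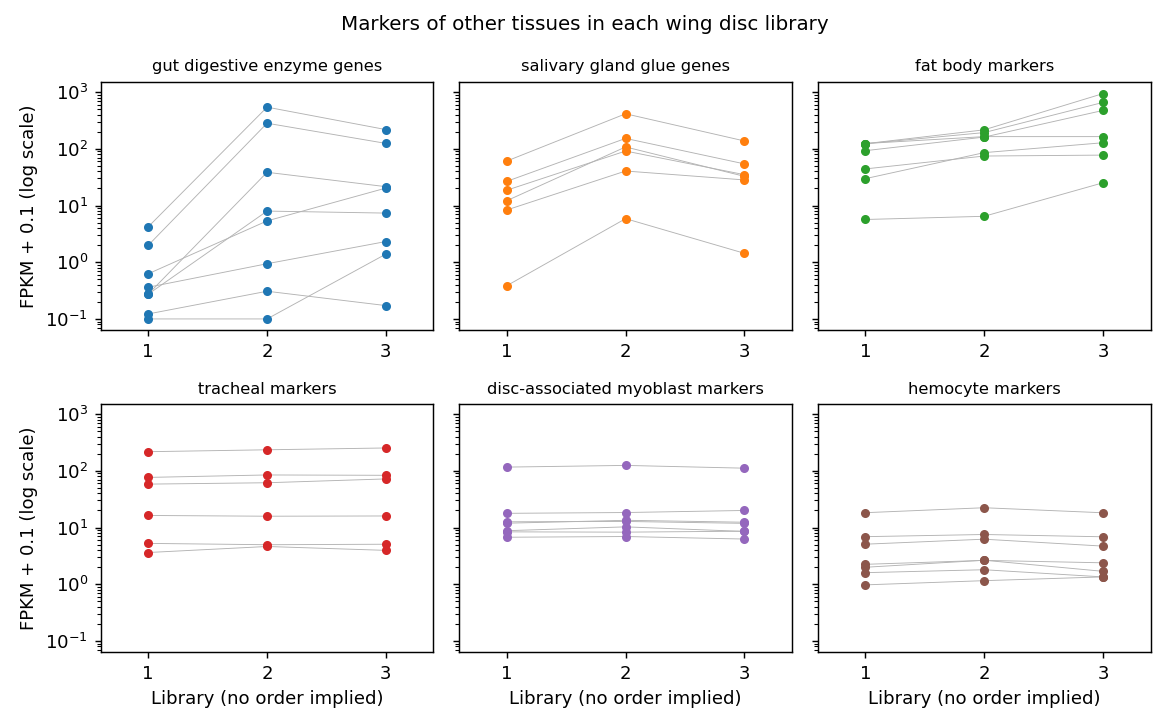
FPKM + 0.1 (y axis, log scale) of the marker genes of 6 tissues in libraries 1, 2 and 3 (x axis, without order). Each point is 1 gene in 1 library and thin lines join the points of a gene. Digestive, glue and fat body genes differed between libraries, as Jon65Aiv did from 4.11 to 542 FPKM, while tracheal, myoblast and hemocyte markers differed less.

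Of 6665 genes with a mean of at least 5 FPKM, 154 (2.31%) differed by more than 2-fold between the highest and lowest library. The antimicrobial-type gene Drsl2 had the largest spread, at 0, 460 and 0.600 FPKM in libraries 1, 2 and 3, and CG10912, CG15818, CG32302, CG33346 and Peritrophin-15b were also highest in library 2. CG42834, CG33333, CG14332 and the odorant-binding protein gene Obp56d were expressed in libraries 1 and 2 and nearly absent from library 3, as CG33333 was at 189, 263 and 0.139 FPKM. All 6 sex-related genes were detected. The male-specific noncoding RNA roX1 (lncRNA:roX1) stood at 88.6, 122 and 56.3 FPKM and lncRNA:roX2 at 10.2, 14.1 and 6.02 FPKM, while Sxl was at 38.4, 36.8 and 40.9 FPKM and tra at 25.3, 22.9 and 25.9 FPKM. The 3 receptor genes of at least 1 FPKM with the largest SD of log2(FPKM + 0.1) were mthl6 (1.97), mthl15 (0.44) and GABA-B-R2 (0.25).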

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

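The number of detected receptor genes was 25 and stayed between 20 and 29 under other FPKM limits, a limit on the mean or on any library, or TPM values. A limit of 1 TPM called the same 29 genes as the limit of 0.5 FPKM. TPM is therefore not a separate check, here or in the family tests. The number was 38 when 10 recovered reads in each library were enough, a criterion that admits lower levels than 1 FPKM. Leaving out each library gave 25 to 26. The limma count was 24, with 23 to 27 under all its alternatives and 23 to 24 without 1 library, and only Rh5, mthl15, mthl2 and rk changed sides. Over all families and alternatives, 80 family tests kept their direction and side of the threshold, 2 lost the call and 8 changed direction. By Fisher's exact test the peptide receptors lost the call with detection in at least 1 library (adjusted p = 0.0778) and with 10 reads (adjusted p = 0.0653). Their detected share rose from 5.88% to 11.8% in the first case, as AkhR and TkR86C were added, and to 17.6% in the second. Families without a call changed direction at a limit of 5 FPKM, namely the class A orphans (adjusted p = 0.882) and the secretin-like and class C receptors (adjusted p = 1 each). Class C also did so, with adjusted p = 1 each time, at 0.5 FPKM, for the mean, for any library, in TPM and without replicate 1. In these alternatives, apart from 5 FPKM, class C stayed at 22.2% detected. The other lists rose from 21.9% to between 22.9% and 25.7%, so a small difference changed sign. The cause of the changes at 5 FPKM was not tested. All 21 gene pairs kept 1 sign across libraries in every alternative. Recovered reads not divided by length reversed the log2 ratio of smo to ptc to -0.14 and of stan to fz to 0.40, by construction. Other pseudocounts moved the ratios of pairs with a member near 0. The percentiles of single lists moved in 60 alternatives and stayed within their spread in 137. That of all receptor genes was 5.92 with both the list and the random lists limited to genes of at least 0.1 FPKM, an alternative chosen after seeing the data that gives the amine receptors no value, since none reaches that mean. Limiting the random lists alone filters unequally and lowers percentiles by construction. The lowest correlation between libraries rose to 0.987 with a pseudocount of 1, chosen after seeing the data like the variance trend and the voom weights, because low genes then count less. No paired analysis was possible because there is a single group. The count-model alternatives planned for a table with counts were not run, since the table holds FPKM. Depth limits the values under about 0.1 FPKM, where 74 of the 114 receptor genes lie.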

Other observations

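Receptors of other structural classes were set beside the GPCR lists, in lists chosen after the data were seen. Of 23 receptor tyrosine and serine/threonine kinase genes 17 were at 1 FPKM or more in every library, against 25 of 114 GPCR genes. After tkv the highest were the Wnt5 receptor gene drl at 103 ± 3.12 FPKM, Egfr at 78.4 ± 1.87 FPKM and the ephrin receptor gene Eph at 62.7 ± 1.33 FPKM (SD, n = 3), while the eye receptor gene sev was at 0.0472 FPKM. Of 186 odorant, gustatory and ionotropic chemoreceptor genes 5 were detected and 121 are listed at 0. Ir76a stood at 12.8 ± 0.564 FPKM, Or43b at 8.26 ± 1.10 FPKM, Gr61a at 4.64 ± 0.402 FPKM, Ir62a at 3.66 ± 0.318 FPKM and Ir68a at 1.20 ± 0.162 FPKM.

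The eye colour gene w stood at 278 ± 10.2 FPKM, above ap at 80.7 ± 1.78 FPKM. Of 8 eye pigment genes, a list chosen after the data were seen, 3 were at 1 FPKM or more in every library, w, ca at 11.3 ± 0.666 FPKM and p at 6.92 ± 0.308 FPKM. The transporter partners of w, st and bw, were at 0.211 and 0.197 FPKM, v was at 0.401 FPKM, cd at 0.055 FPKM, and cn had no read. In fly stocks w is commonly carried as a marker on transgene insertions, and whether these reads come from an insertion or from the X-linked gene was not tested.

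In the 3 patterns that follow, the tests of fat body genes outside the fixed list and of other long noncoding RNAs were set before their results were seen, and the other tests were chosen afterwards.

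Digestive, glue and fat body transcripts differed between libraries, as Jon65Aiv did from 4.11 to 542 FPKM. A difference in scaling or depth is argued against, since the recovered reads before any scaling had a largest median log2 ratio between libraries of 0.089 over 7931 genes of at least 1 FPKM, against a median range of 2.73 for the 21 genes of these lists. Gut RNA carried along with the discs is a candidate explanation for the digestive part: of 38 digestive genes outside the fixed list, 37 had a read, and 36 of these were higher in the mean of libraries 2 and 3 than in library 1, with a median log2 ratio of 1.8 (quartiles 0.77 and 3.18). For the fat body part the median log2 ratio of library 3 over the others was 0.12 over 5 genes outside the fixed list. By the rule set beforehand, a median this low counted against fat body RNA carried along in library 3. The 5 genes went both ways (-2.31 to 1.19) and 3 of them were higher in library 3, so the question was left open. The design has 1 group, so no biological explanation was tested, and differences in stage or feeding between the pools remain possible.

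The 25 detected receptor genes might be expressed in tissue other than the disc epithelium. RNA of the tissues that differ between libraries is argued against for the set as a whole, because the median ratio of the highest to the lowest library was 1.11 over the 27 receptor genes with a mean of at least 1 FPKM. The exception was mthl6, the 1 gene of these that exceeded 2, at 14.5. Choosing genes by level leaves out low genes that vary, so the result does not cover them. AkhR and TkR86C, with means under 1 FPKM and their highest values in library 3, had ratios of 5.72 and 2.08. Tissue attached at a steady share cannot be told apart from the epithelium here. Of 20 tracheal, myoblast and hemocyte markers, 19 were at 1 FPKM or more in every library. The median SD was 0.21 for the hemocyte markers and 0.07 for the detected receptor genes. Random lists matched on level had median SDs of 0.16 and 0.06, which placed these lists at percentiles 67.4 and 69.3. The tracheal and myoblast markers had median SDs of 0.09 and 0.08, against 0.06 and 0.07 for matched lists (percentiles 87.8 and 71.2). Such percentiles depend on the size of a list, and the hemocyte list has 7 genes against 25 receptor genes. They therefore do not show which list varied more relative to genes of like level.

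The noncoding RNAs roX1 and roX2 and the gene msl-2, parts of the male dosage compensation complex, were higher in library 2 than in library 3 by 1.11, 1.21 and 0.51 on the log2 scale. A shift of long noncoding RNA by library preparation is argued against, as 54 other long noncoding RNAs had a median log2 ratio of -0.014 (quartiles -0.18 and 0.12). Of Sxl, tra and dsx, 3 of 3 had the opposite order of libraries. These differences were small, and FPKM per gene does not separate the transcript forms of a gene. The test was also chosen after the data were seen, so it cannot decide whether the pools held different shares of male larvae. The labels give no sex, so a different share of males stays a hypothesis.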
